A study of Mus musculus with 4 samples.

How the data were processed

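The assay was ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA. It was applied to nuclei of mouse bone marrow-derived macrophages from 2 genotypes. Knockout (KO) cells came from mice with a floxed Ezh2 gene and Cre recombinase under the control of the Lyz2 locus (LysM-Cre), and wild-type (WT) cells came from littermate controls. Per the labels, marrow was cultured for 7 to 10 days with L929 cell medium as the source of macrophage growth factor. All 4 libraries analysed here were exposed for 24 hours to medium conditioned by Hepa1-6, a mouse liver cancer line. Libraries without that exposure were not analysed here. There were 2 libraries per genotype, sequenced as paired 150 bp reads, and each library was placed in its group by its title. The labels do not say whether replicates came from separate mice or cultures, so each SD given here measures only the spread between these libraries. The intervals given here do not measure that spread.

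The submitters' processing notes name fastp for read trimming, Bowtie2 for alignment, MACS2 for peak calling and mm10 as the genome build, without the tool versions, which are not given in the sources used here. The deposited files are 4 broad peak lists, 1 per library and not pooled across replicates. Whether reads were shifted for the transposase, which reads were removed, and what filter was applied to the peaks is not given in the sources used here. Each list skips between 261 and 322 of its own peak numbers, which shows that some peaks had been taken out after calling. The score of each peak in the deposited lists is a whole number derived from its −log10 q. The fold value is, by the layout of the deposited lists, the enrichment of the peak over the peak caller's local background, averaged over the peak. It is the authors' own value and was used only to describe, rank or filter peaks within a list. The deposited −log10 p and −log10 q columns give the peak caller's p-value and q-value, and the largest q in any list was 0.0497. The files give no read counts and no coverage, so the sequencing depth is unknown. A peak missing from a list may therefore reflect the depth of that library, and no reading of signal was possible where no peak was called.

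All 4 lists were merged into union regions wherever peaks overlapped by at least 1 bp. A library was said to call a region when 1 of its peaks overlapped it. KO-only regions were called in both KO libraries and in neither WT library, WT-only regions were the reverse, and crossing regions were called in exactly 1 library of each genotype. The 4 libraries can be split into pairs in 3 ways, of which 1 follows genotype. The genotype ratio is the square root of the ratio between the product of the pair counts that follow genotype and the product of the pair counts of a crossed split. Differences between libraries in the odds of calling a peak cancel in this ratio. With 2 libraries against 2, the smallest two-sided exact p for a single region is 0.333, so no test was run per region. Strength of a region is the smaller of its calling libraries' within-list percentiles of fold. Shares carry exact Clopper-Pearson intervals at 95% confidence, and ratios carry Wald intervals on the log scale. All intervals cover counting error only. Similarity between libraries was measured as the Jaccard index of covered bases.

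Genes were placed with the NCBI RefSeq table of GRCm38.p6, the assembly behind mm10, which holds 21900 protein-coding genes with their start and end but neither strand nor exons. The planned distances to transcription start sites were therefore replaced by distances to the nearest annotated end, at either side, of a protein-coding gene. A region was assigned to that gene when the distance was at most 50 kb, and was called a gene-end region when it lay within 1 kb. A gene-end region can thus lie at the 5′ or the 3′ end of a gene, or at a neighbouring gene whose end is close by. A gene without a gene-end region can still have called regions elsewhere inside it or nearby. No genome sequence was used here, so the planned comparison of 20 motifs was not run.

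Before the data were examined, 20 gene lists with 385 genes were fixed, along with the groups, the main comparisons and most alternatives. They covered alternative (M2) and inflammatory (M1) activation, tumour-associated macrophages, the interferon response, macrophage identity, antigen presentation, lipid handling, Polycomb repressive complex 2 (PRC2), Hox genes, other developmental regulators, the cell cycle and markers of other cell types. Cxcl11, Mx1 and Mx2 are classed as transcribed pseudogenes in the table and were left out. For each list and direction, the share of assigned regions that were genotype-only was compared with all other assigned regions by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 40 tests. A further test drew 10000 random gene lists matched on the number of assigned regions. A gene was counted as called at its ends in all 4 libraries when each library called a region within 1 kb of either end, which need not be the same region in each. The share of such genes was compared between each list and all other protein-coding genes by the same kind of test, adjusted over 20 lists; this comparison was added after the data were seen. Gene-end shares of KO-only and WT-only regions were compared with crossing regions by Fisher's exact test. Genes with 3 or more genotype-only regions were counted against 10000 shuffles of the labels among 2-library regions of the same chromosome. Regions and genes are not replicates, so these tests describe these 4 libraries.

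The genes named in the text followed a rule fixed in advance. It took Ezh2, the PRC2 list and Lyz2, the 12 strongest KO-only and 12 strongest WT-only regions with 1 region per gene, up to 6 members per direction of the 4 activation lists and of any list past the test, and the 5 genes per direction with the most genotype-only regions. Values of some single genes on these lists are not reported here. Genes named outside this rule, as examples of called or uncalled list members or in the closing section, were chosen after their values were seen. For the closing section each list was reduced to its 67055 peaks of highest −log10 q, and within-list percentiles of fold were compared for regions called in all 4. Differences were centred within 20 bins of mean percentile, and lists were tested against 10000 random gene lists matched on the number of such regions.

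Alternatives covered the coverage a call needs, gaps up to 500 bp, removal of the weakest 25% or 50% of each list by −log10 q, equal numbers of peaks, a threshold for presence only, other windows and backgrounds, and leaving out each library. The counts of KO-only and WT-only regions with both calls in the upper 50% by fold were planned. The genotype split within subsets by percentile of fold, the subsets by peak width and autosomes, the list-wise gene-end comparison and the rank comparison, with its version within numbered pairs, were chosen after the data were seen.

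The code was tested on simulated calls over the 91858 union regions with no genotype difference, 100 runs for each of 2 ways in which libraries may differ. In the simulation written first, each library scaled the chance of a call. There the genotype ratio averaged 0.985, and its intervals held 1 in 76% of runs against the split that paired equal replicate numbers, where the mean was 0.973, and in 95% against the other split. Some gene list was called in 10 of the 100 runs. After this result a second simulation was added, in which each library scaled the odds of a call, the case for which the ratio is exact. It gave a mean of 0.993 and 93% of intervals that held 1, and some gene list was called in 3 of 100 runs, or in 5 with the chance of a call shuffled among regions. Which case holds for the real libraries is unknown. If libraries scale the chance, the ratio against the split that paired equal replicate numbers is shifted below 1 in the simulation, and its intervals miss 1 more often than stated; the largest simulated ratio in that case was 1.05. Under the second simulation all 200 planted KO-only regions were recovered. They were set as called in both KO libraries and neither WT library, so their recovery checks the code only. The M2 list with 15 planted regions was called in 100 of 100 runs, with another list called in 11. The real M2 list had 4 KO-only regions, so 15 planted regions leave open whether a smaller effect would be found.

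Computations used own code in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.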

Results

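Accessible chromatin was profiled by ATAC-seq in bone marrow-derived macrophages that had been exposed to medium from Hepa1-6 liver cancer cells for 24 hours. WT macrophages were compared with macrophages from Ezh2 knockout mice, with 2 libraries per genotype. Ezh2 is the catalytic subunit of PRC2, which methylates lysine 27 of histone H3 and keeps developmental genes silent. The lists held 69210 and 72887 peaks in the WT libraries and 67055 and 71111 in the KO libraries, which gave means of 71049 ± 2600 and 69083 ± 2868 (SD, n = 2 each). Covered sequence was 28.8 ± 1.49 Mb in WT and 28.3 ± 2.26 Mb in KO, so the genotypes differed by less than their replicates did. Merged across libraries, the peaks formed 91858 regions on mm10. Of these, 53062 (57.8%) were called in all 4 libraries and 21138 (23.0%) in a single library. Regions called everywhere had a median width of 513 bp, against 156 bp for those called once. The width is the span of all merged peaks, so part of this contrast is built in.

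Macrophages of both genotypes had peaks at the ends of genes that define the lineage. Among 23 macrophage identity genes, 21 had a gene-end region in each of the 4 libraries, not necessarily the same one, including Spi1 (encoding PU.1), Cebpa, Cebpb, Csf1r (the receptor for macrophage colony-stimulating factor), Irf8 and Adgre1 (encoding F4/80). Only Ccr2 and Mef2c of this list had none in any library. This share of 91.3% (95% CI 71.96 to 98.9) exceeded the 54.7% found over all protein-coding genes (Fisher's exact test, adjusted p = 0.00148). The share was also higher for genes of tumour-associated macrophages (22 of 25, exact test, adjusted p = 0.00284). Vegfa, Hif1a, Spp1, Trem2, Apoe and C1qa were among those called at a gene end in every library. Ldha, Mmp9 and Mmp12 had no gene-end region in any library, but each had 3 assigned regions called in all 4. By the same exact test the share was higher for inflammatory activation (25 of 30, adjusted p = 0.00320), the interferon response (18 of 20, adjusted p = 0.00287), lipid and cholesterol handling (18 of 20, adjusted p = 0.00287) and the cell cycle (19 of 21, adjusted p = 0.00266). Nos2, Tnf and Il6 of the inflammatory list, Ifit1 and Irf7 of the interferon list and Abca1 of the lipid list were called at a gene end in all 4 libraries. With the weakest 50% of each peak list removed, the interferon list no longer passed (exact test, adjusted p = 0.0617). The alternative activation list stood at 19 of 30 genes (63.3%, CI 43.9 to 80.1, exact test, adjusted p = 0.406). Arg1, Mrc1 (the mannose receptor), Il10, Pparg, Stat6 and Klf4 belonged to the 19, while Retnla, Chil3, Chil4, Cd163 and 4 others had no gene-end region in any library. Antigen presentation genes stood at 12 of 16 (exact test, adjusted p = 0.177), with Cd74 and Ciita uncalled at their ends.

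Genes silenced by Polycomb complexes in most tissues were at the other extreme, in both genotypes. Of 39 Hox genes, 5 had a gene-end region in each of the 4 libraries and 30 had none in any (Fisher's exact test, adjusted p = 9.59e-07). Hoxa3, Hoxa4, Hoxa10 and Hoxb8 were among those called throughout. Of 56 other developmental regulators, 7 were called in all 4 libraries and 37 in none (exact test, adjusted p = 1.72e-09). Bmp2, Gsc, Lhx2, Meis1, Tbx3 and Wnt1 were among the 7, and Pax6, Sox2, Sox9, Gata4, Foxa2 and Nkx2-1 were among the 37. Cdkn2a and Cdkn2b, cell cycle inhibitors often used as readouts of PRC2 loss, had gene-end regions in both genotypes. Marker lists of other cell types did not differ from all genes after adjustment (exact test, adjusted p from 0.0925 to 1.0). With the weakest 50% of each peak list removed, however, the shares were lower than elsewhere for B cell markers (exact test, adjusted p = 0.00977) and for T and NK cell, dendritic cell and hepatocyte markers (adjusted p = 0.0475 each). The counts of genes with a gene-end region in each library were 4 of 12 for neutrophils, 2 of 10 for B cells, 4 of 14 for T and NK cells, 5 of 10 for dendritic cells, 2 of 9 for mast cells, basophils and eosinophils, 2 of 7 for osteoclasts, 2 of 9 for fibroblasts, 2 of 10 for hepatocytes and hepatoma and 4 of 8 for erythroid cells. Alb and Afp, abundant in liver cells, did not have a gene-end region in all 4 libraries. Alb was called in WT replicate 1 and KO replicate 1, and Afp in none.

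**Figure D1:**
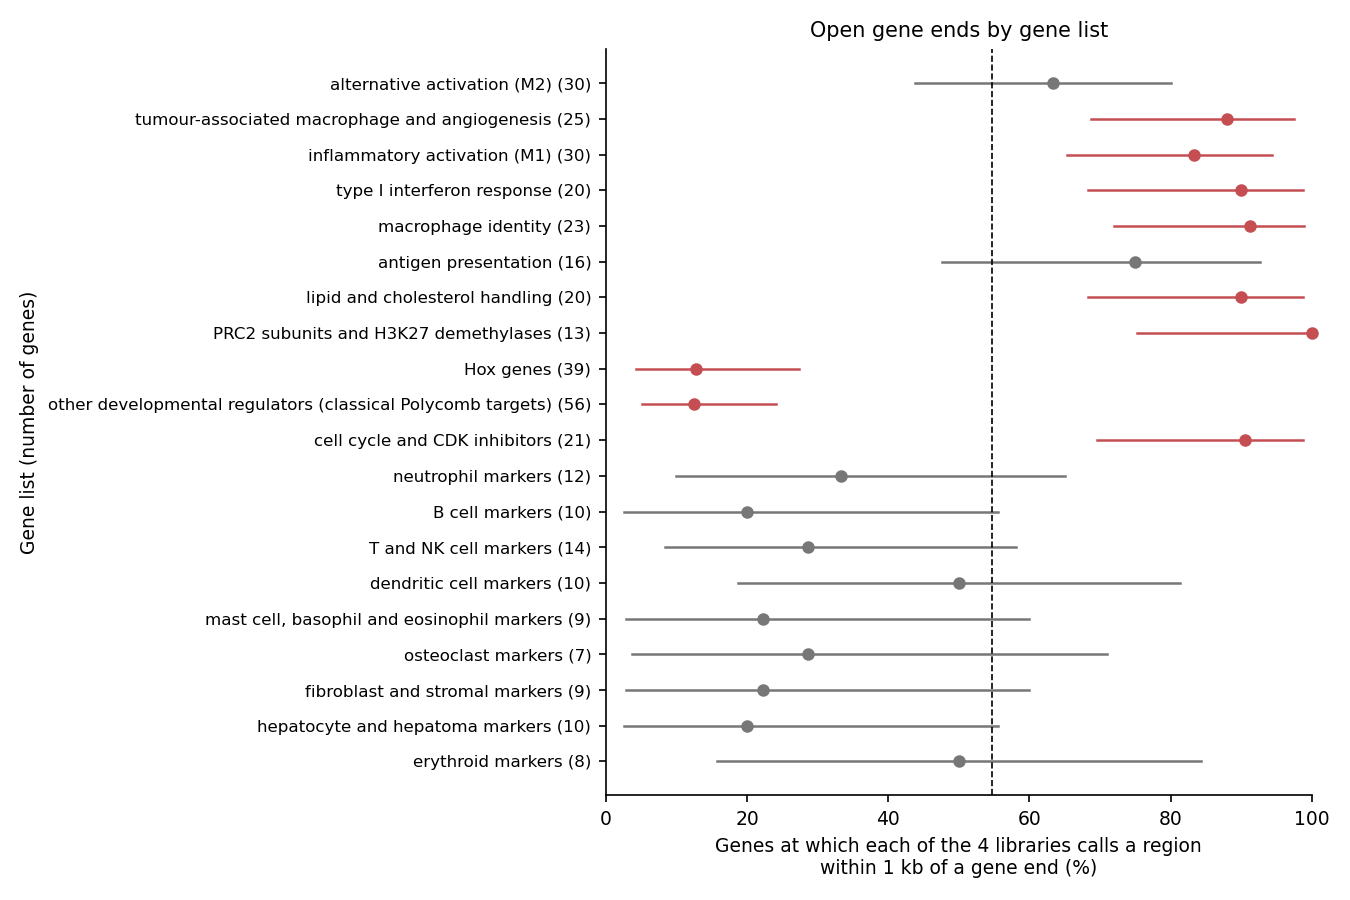
Share of genes in each list (%, x axis) at which each of the 4 libraries calls a region within 1 kb of a gene end, not necessarily the same region; points are shares, lines are 95% Clopper-Pearson intervals, and the dashed line marks all protein-coding genes (54.7%). Red marks an adjusted p under 0.05 (Fisher's exact test); macrophage identity stands at 91.3% and Hox genes at 12.8%.

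The knocked-out locus was still called at its gene end. Ezh2 (chromosome 6, 47530274 to 47595270) had a region of 1455 bp at its higher-coordinate end, 47594084 to 47595538, in all 4 libraries, with deposited fold values of 5.52 and 5.15 in WT and 6.24 and 5.62 in KO. A region inside the gene, 2221 bp from its lower-coordinate end (47532495 to 47532897), was also called in every library but with unlike peaks. Its WT peaks spanned 403 and 372 bp with fold values of 5.66 and 7.10, and its KO peaks spanned 106 and 182 bp with fold values of 3.61 and 3.42. Within their own lists these values fell at percentiles 73.7 and 92.7 in WT and 24.9 and 23.4 in KO. The exons under this region were not analysed here. The remaining region of Ezh2 called in all 4 libraries, 47562290 to 47562677, had fold values of 3.71 and 4.12 in WT and 4.25 and 3.22 in KO. Of the 6 regions inside the gene, 3 were called in all 4 libraries and 3 in a single library.

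**Figure D2:**
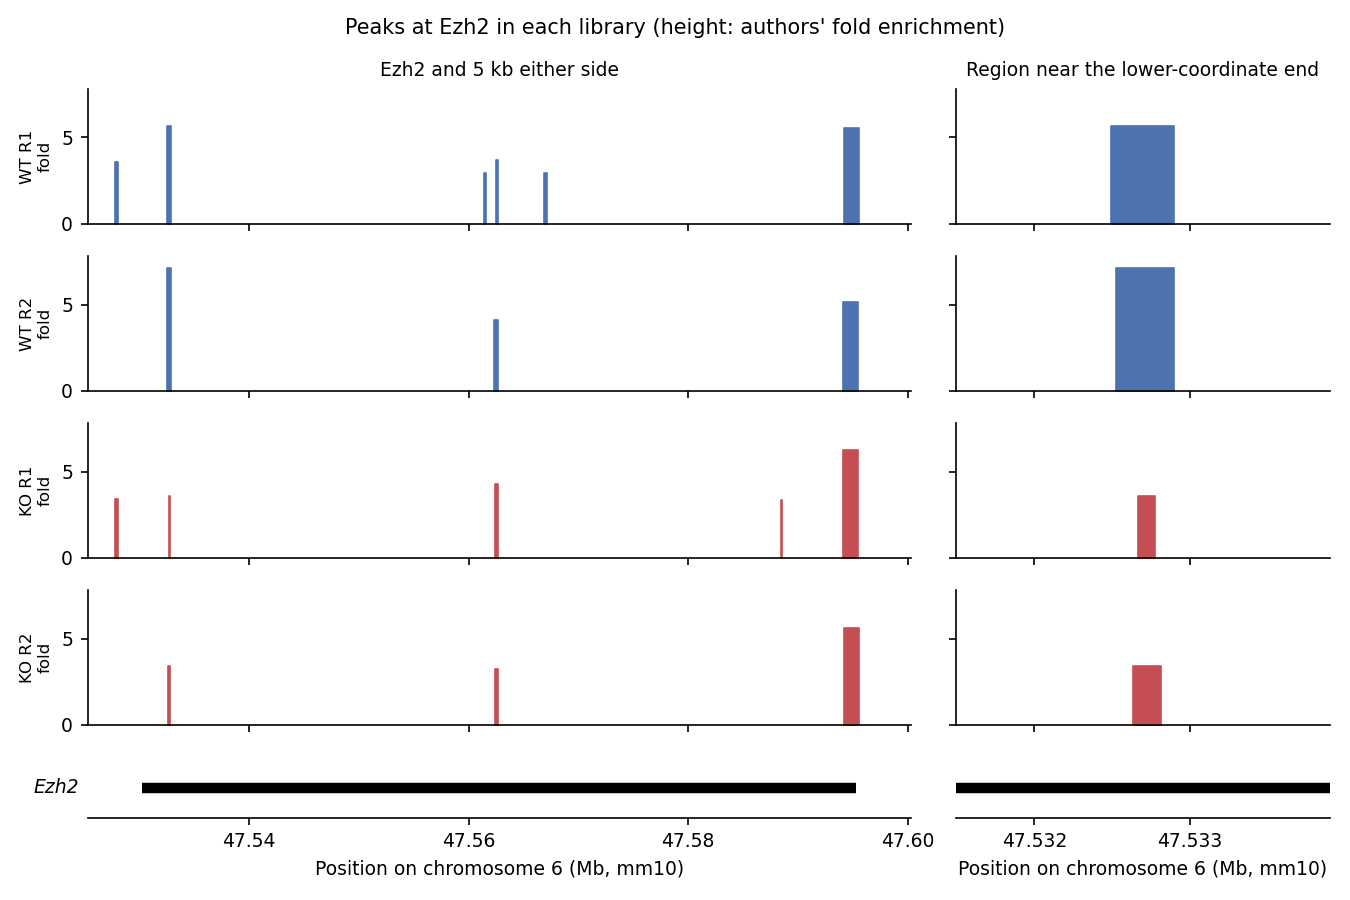
Peaks called at Ezh2 in each library along chromosome 6 (x axis, Mb, mm10); bar height is the authors' fold enrichment of the peak, with WT in blue, KO in red and the gene as a black bar. The right panels enlarge the region from 47532495 to 47532897, where WT peaks reach fold values of 5.66 and 7.10 and KO peaks 3.61 and 3.42.

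All 13 genes of the PRC2 and H3K27 demethylase list had a gene-end region in all 4 libraries, among them the paralog Ezh1, the core subunits Eed and Suz12, and the demethylases Kdm6a and Kdm6b (Fisher's exact test against all genes, adjusted p = 0.00211). Genotype-only regions on this list were limited to Aebp2, with 1 KO-only and 1 WT-only region, and Kdm6a, with 1 WT-only region 4777 bp from its end. Both regions at Lyz2, the locus that carries Cre in the KO mice, were called in all 4 libraries. Peaks on chromosome Y numbered 64 and 74 in WT and 69 and 76 in KO. A region inside Xist was called in all 4 libraries and none was called at its ends, so the libraries did not differ in these marks of sex.

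The main question was which regions were called in 1 genotype only. KO-only regions numbered 1350 and WT-only regions 1867, which is 1.47% and 2.03% of all regions. Pairs of libraries that crossed genotype gave counts in the same range, from 959 to 2050. Of the 8911 regions called in exactly 2 libraries, 3217 followed genotype (36.1%, CI 35.1 to 37.1), against 3009 and 2685 for the crossed splits. The genotype ratio was 1.13 (1.07 to 1.19) against the split that paired equal replicate numbers and 1.18 (1.12 to 1.25) against the other, while the crossed splits stood at 1.05 to each other. In simulations where libraries differed in the chance of a call rather than its odds, the ratio against the former split averaged 0.973, and its intervals held the true value of 1 in 76% of runs, while those against the other split did in 95%. With 3 possible splits, the smallest p that the order of these values can give is 0.333. Similarity between whole libraries overlapped within and across genotypes. The Jaccard index was 65.1% and 65.4% within WT and within KO and from 64.1% to 65.6% between genotypes, a difference of means of 0.212 percentage points. By the share of overlapping peaks the excess within genotypes was 0.994 points, where the SD over all pairs of libraries was 0.944. By reciprocal overlap of 50% it was 0.840 points, with an SD of 0.489. These measures are on unlike scales. Leaving out a library leaves its genotype with a single call to meet and its counterpart with a single absence. KO-only regions then numbered 2899 without WT replicate 1, 3606 without WT replicate 2, 7106 without KO replicate 1 and 5298 without KO replicate 2, and WT-only regions 8696, 6472, 3619 and 5057 in the same order.

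Most genotype-only calls were weak, as were other regions called in 2 libraries. The median within-list percentile of the weaker call was 11.7 for KO-only and 14.98 for WT-only regions, against 13.3 for all regions called in exactly 2 libraries and 49.3 for regions called in all 4. Regions under 150 bp made up 18.4% of KO-only and 21.2% of WT-only regions but 0.626% of those in all 4. As a region spans all its merged peaks, part of this contrast is built in too. Where both calls had a percentile of 50 or more, 35 KO-only and 82 WT-only regions were left beside 22 to 46 for the crossing pairs. The genotype ratio there was 1.68 against either crossed split (1.22 to 2.32 and 1.22 to 2.30), a ratio computed after the data were seen. 

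**Figure D3:**
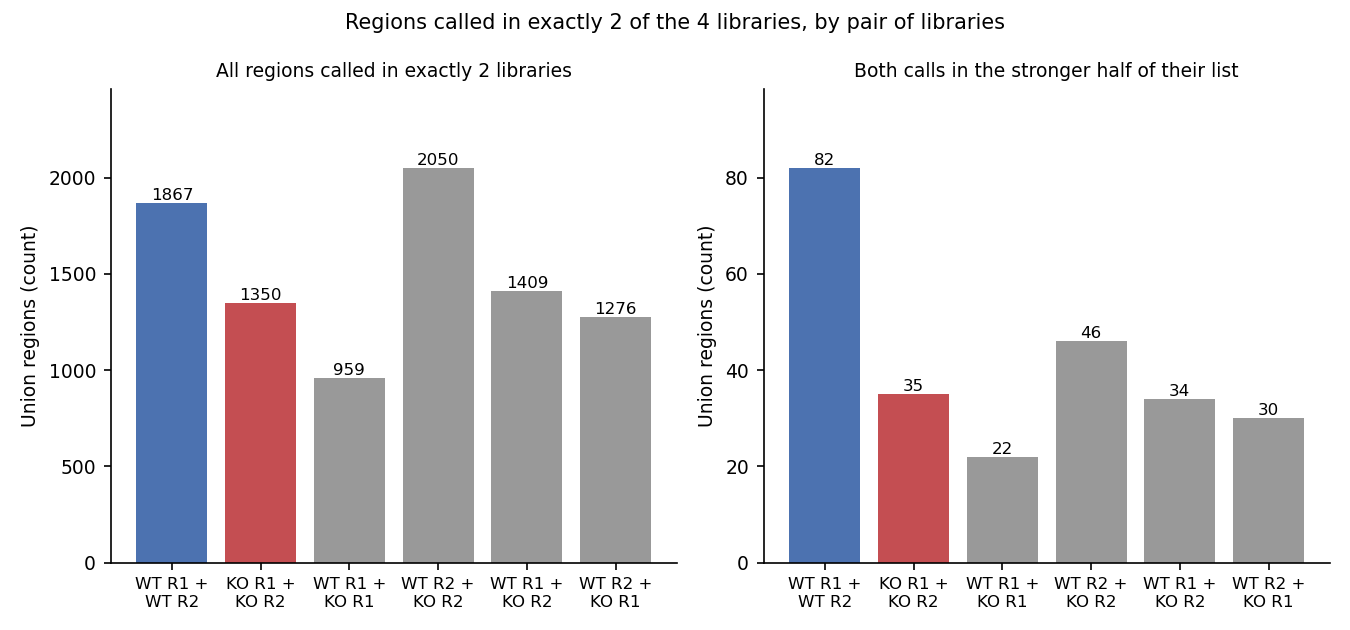
Number of union regions (y axis) called in exactly 2 libraries, for each pair of libraries; WT pair in blue, KO pair in red, pairs that cross genotype in grey. Over all such regions the WT pair has 1867 and the KO pair 1350, within the range of 959 to 2050 for the crossing pairs; with both calls at percentile 50 or above the WT pair has 82 and the KO pair 35.

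The strongest KO-only regions lay near Polr3b, which encodes an RNA polymerase III subunit (chromosome 10, 84631320 to 84631465), Serpinb1c, Akap6, Crim1, Zfr, Fmnl2, Rbm20, Nemf, Glg1, Slc26a8, Sat1 and Fzd2. Their strength ran from 55.2 to 75.2, and 9 of the 12 were under 150 bp wide. The widest was the 804 bp region at an end of Fzd2, a Wnt receptor gene (chromosome 11, 102603692 to 102604495), with fold values of 4.85 and 4.63 in the KO lists. At Rbm20, which encodes a splicing regulator, a KO-only region of 647 bp lay inside a gene (chromosome 19, 53824661 to 53825307), with fold values of 5.01 and 6.76. Sat1 encodes an acetyltransferase that drives polyamine breakdown, and its KO-only region of 116 bp lay 17880 bp from the gene. Among the KO-only regions, Fzd2 and Zfr also belonged to the genes with the most such regions, with 2 each, as did Rims2, Nxpe5 and Galnt9.

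The strongest WT-only regions lay near Chordc1, an Hsp90 cochaperone gene (chromosome 9, 18277612 to 18277759), Cetn3, Plpp3, Heatr5b, Sec61g, Oxr1, Mocs2, Gpcpd1, Sms, Rlf, Frg1 and Serpinb8. Their strength ran from 66.0 to 75.5, and they were 126 to 236 bp wide. Sms, the spermine synthase gene, had its WT-only region of 126 bp at 157486897 to 157487022 on chromosome X. None of the 12 lay within 1 kb of a gene end, and 1 of the 12 KO-only regions did. Rbpj (the transcription factor of Notch signalling), Hmga2 and Kmt2c (an H3K4 methyltransferase gene) had 3 WT-only regions each, and Chordc1 and Gpcpd1 had 2. No gene had 3 KO-only regions, where shuffled labels gave 1.64 on average (one-sided permutation p = 1.0), and 3 genes had 3 WT-only regions, where shuffled labels gave 4.09 (p = 0.782). With at least 2 regions per gene, the KO-only count was above the shuffled mean, at 46 against 41.0 (permutation p = 0.210), as it was with 3 regions within 100 kb, at 4 against 3.95 (p = 0.565).

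Macrophage activation genes had few genotype-only regions, and these went in both directions. The alternative activation list had 204 regions, of which 135 were called in all 4 libraries, 4 were KO-only and 3 WT-only. The KO-only regions were near Il10 (194 bp, 4189 bp from the gene), Cd200r1, Clec10a and Chil4, and the WT-only regions were 2 near Cd200r1 and 1 near Cd163, a scavenger receptor gene. Tumour-associated macrophage genes had 1 KO-only region, of 616 bp and 2908 bp from Vegfa (chromosome 17, 46013470 to 46014085), and no WT-only region among 137. The inflammatory list had 2 KO-only regions, near Il12a and Irf1, and 4 WT-only regions, near Il12a, Cxcl9 and Il12b, among 203. Of 66 interferon response regions, 3 were KO-only (4.55%, CI 0.947 to 12.7), against 1.39% of all other regions. These lay near the interferon-induced genes Ifit2, Ifit3 and Oas1a, and had the smallest p of the 40 tests (Fisher's exact test, p = 0.0650, adjusted p = 1.0). A single WT-only region of 145 bp lay at Isg15, another interferon-induced gene.

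Developmental genes had as many WT-only as KO-only regions outside the Hox clusters. Of 176 regions near developmental regulators other than Hox genes, 3 were KO-only, near Olig2, Neurog2 and the brachyury gene, and 3 WT-only, near Emx2, Pax8 and Tbx2 (1.70% each, CI 0.353 to 4.90). Hox genes had 1 KO-only region, 39579 bp from Hoxb1, and 2 WT-only regions, near Hoxa10 and Hoxc9, among 30. The macrophage identity list had 1 KO-only region, near Mertk, and 6 WT-only regions, near Irf8, Zeb2, Runx1 and Mitf, among 220. Among lipid genes, Abca1 had a KO-only region, and Acaca, Cd36 and Lipa had WT-only regions. Cell cycle genes had 1 of each, near Mcm2 and at Mki67. For markers of other cell types, the KO-only and WT-only counts were 1 and 1 for B cells, 2 and 1 for T and NK cells and 1 and 1 for mast cells, basophils and eosinophils, whose KO-only region of 506 bp lay at an end of Gata2. Dendritic cell and fibroblast markers had no KO-only and 1 WT-only region each, near Flt3 and Col1a1. Antigen presentation, neutrophil, osteoclast and hepatocyte genes had none in either direction. None of the 40 tests passed an adjusted p of 0.05 by Fisher's exact test or with matched random lists, and 0 did so unadjusted by either. Leaving out replicate 1 of a genotype, so that 1 library stood for it, gave higher shares for developmental regulators. Without WT replicate 1, 19.5% of their regions were called in WT replicate 2 alone of the remaining libraries, against 8.88% of other regions. Without KO replicate 1, 15.7% were called in KO replicate 2 alone, against 7.26%, and for T and NK cell markers the share was 23.3%. However, 33.0% of developmental regulator regions and 51.1% of T and NK cell regions were called in all 4 libraries, against 60.9% of all assigned regions. Lists with fewer shared regions leave more for calls in few libraries, so these shares cannot be read as a genotype difference.

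At gene ends, the genotypes had nearly equal numbers of specific calls. Both KO libraries and neither WT library called a gene-end region at 65 genes, and the reverse at 69 genes, with 32 to 89 genes for the crossing pairs. Among the list genes, Gata2 belonged to the former and Isg15 and Tbx2 to the latter. The weaker call at each lay near the bottom of its list, at percentile 2.84 for Gata2, 1.04 for Isg15 and 0.977 for Tbx2. Of KO-only regions, 7.85% (CI 6.47 to 9.42) lay at a gene end, against 6.64% (6.01 to 7.32) of crossing regions (Fisher's exact test, p = 0.120). For WT-only regions the share was 6.21% (5.16 to 7.41, exact test, p = 0.553), and for regions called in all 4 libraries 22.3% (22.0 to 22.7, p = 2.74e-210). Without WT replicate 2 the KO-only difference from crossing regions was 1.24 percentage points (exact test, p = 0.0189), and without KO replicate 2 the WT-only difference was -1.09 points (p = 0.0232), both past 0.05. The WT-only difference, negative over all peaks, turned positive at 50% coverage (0.120 points) and with the weakest 25% or 50% of each list removed (0.814 and 0.764 points), with exact p of 0.847, 0.348 and 0.495.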

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

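Alternatives that used a minimum width, a minimum percentile of fold for the genotype share, autosomes only, gene bodies, list-wise gene-end counts or ranks were chosen only after the data were seen. KO-only regions numbered 2031 when a call had to cover 50% of the region, 879 and 702 with the weakest 25% and 50% of each list removed, 35 with both calls in the upper 50% by fold, and 267 with peaks of at least 200 bp. WT-only regions numbered 981 with the weakest 50% removed, 82 in the upper 50% and 315 at 200 bp. Leaving out 1 library gave 2899 to 7106 KO-only and 3619 to 8696 WT-only regions, because fewer libraries had to agree. The share that followed genotype was 35.0% at 50% coverage, 37.6% with the weakest 25% or 50% removed, 38.6% and 47.0% with both calls at percentile 25 or 50 and above, and 34.1% at 200 bp. At 200 bp, 582 regions followed genotype, fewer than the 621 of the split that paired equal replicate numbers and more than the 505 of the other. The genotype ratios there were 1.12 (0.989 to 1.27) and 1.15 (1.02 to 1.29), and the former interval held 1. The excess of similarity within genotypes was 0.994 points by overlapping peaks and 0.840 points by reciprocal overlap of 50%. The WT-only gene-end difference changed sign, to 0.120 points at 50% coverage and 0.814 and 0.764 points with the weakest 25% and 50% removed, with p above 0.05 in each; over omitted libraries it ran from -1.09 to -0.0160, and the KO-only difference from 0.603 to 1.24. Gene list tests past the threshold stayed at 0 except when a library was left out. Without WT replicate 1, 19.5% of regions of other developmental regulators were called in WT replicate 2 alone, against 8.88% of other regions. Without KO replicate 1, 15.7% were called in KO replicate 2 alone, against 7.26%, with a raised share for T and NK cell markers too. Fewer regions of both lists were called in all 4 libraries, so these shares cannot be read as a genotype difference. Genes with several KO-only regions moved above the shuffled mean, to 46 with at least 2 regions and 4 within 100 kb, neither past the threshold. Of the 24 named regions, 2 had both peaks at least 200 bp wide. Apart from the omission of libraries, where fewer calls are needed, and stricter filters, which leave fewer peaks, the cause was not tested. Of the values from alternatives fixed in advance, 38 stayed within the margin, 21 moved beyond it, 5 changed direction and 2 newly passed 0.05. The margin was a fixed fold range for counts, the main interval for the genotype share and the SD over pairs for similarity. Tests stayed within it if their direction and their side of 0.05 held, and gene list tests if the number past the threshold held. Some outcomes were built in. The named regions keep their class when any library is left out, and the counts of genotype-only regions can then only rise. The 9 gene lists with a differing share of called gene ends were shared in 9 of 9 cases with equal numbers, 2.5 kb and each library left out, and in 8 cases with the weakest 50% removed, which lost the interferon list and added B cell, T and NK cell, dendritic cell and hepatocyte markers. The planned motif comparison was not run. No paired analysis was possible for presence calls because a region that differs the same way in both numbered pairs is by definition called in both libraries of 1 genotype and neither of the other, and no test gives that result. Depth is unknown, so a region absent from a list cannot be told from one under the caller's limit.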

Other observations

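Comparisons of ranks in lists of equal length, also within numbered pairs, and of the genotype split among strong calls were chosen only after the data were seen, as were the tests on Ezh2 and on chromosome 6. Among regions called in all 4 libraries, the ranks of osteoclast genes were lower in the KO lists. Mean centred rank difference over 21 regions of 6 genes was -6.79 percentile points (permutation test against matched random lists, p = 0.00260, adjusted p = 0.0400 over 20 lists), and 3 of the 21 regions lay above 0. All 6 genes were lower on average, with -18.4 points at Acp5 (encoding tartrate-resistant acid phosphatase), -15.6 at Ocstamp, -7.41 at Oscar, -6.90 at Ctsk (cathepsin K), -3.48 at Nfatc1 and -0.641 at Dcstamp. Of these, Ocstamp has 1 region and rests on KO replicate 1, at -28.1 centred points against 9.75 in KO replicate 2 and 9.08 and 3.84 in WT. Dcstamp turns without KO replicate 2, as KO replicate 1 stands at 1.26 against -0.257 and 0.881 in WT. The crossed splits gave -0.0714 and -1.20 points for this list, and leaving out 1 library gave -7.42 to -6.15. Within the numbered pairs, which the labels do not say were handled together, the differences were -7.99 and -5.58. Macrophage identity genes had higher ranks in KO, by 2.74 points over 153 regions (permutation p = 0.00400, adjusted p = 0.0400). The genotype-only regions of this list, which the ranks leave out, leaned the other way. Of 220 regions 1 was KO-only and 6 were WT-only, some of them near Mitf and Zeb2, with neither share past 0.05 by exact test. Single genes stood at 9.23 points for Mitf, 7.99 for Fcgr1 and 7.39 for Zeb2 but -4.02 for Lyz2. Zeb2 rests more on KO replicate 1, at 7.79 against -1.81 in KO replicate 2 and -1.56 and -7.24 in WT. Lyz2, with 2 regions, turns without KO replicate 2, which stands at -7.96 against 4.66 in KO replicate 1 and 6.55 and -1.81 in WT. The difference of the whole list rested more on KO replicate 1, as it was 1.15 points without that library and 4.32 without KO replicate 2, or 4.21 and 1.26 within the numbered pairs. The crossed splits gave -1.70 and 1.47 for this list, and the former lies outside the range of matched random lists (-1.46 to 1.87), so a split unrelated to genotype also passed that range. Cell cycle genes stood at -2.48 points (permutation p = 0.0480, adjusted p = 0.320), and the other 17 lists had adjusted p above 0.05.

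Single regions with large rank differences were more frequent for genotype than for the crossed splits. A gap of at least 20 percentile points separated both libraries of 1 genotype from both of the other at 616 of 52144 regions, against 441 and 416 for the crossed splits, and a gap of at least 40 points at 11, against 4 and 1. The largest gap in favour of KO, 58.5 points, was near Bmf, a pro-apoptotic gene of the BCL2 family (chromosome 2, 118554474 to 118555033), followed by Nxpe4, Cep120 and Rgs3. The largest in favour of WT, 59.7 points, was near Tacc1 (chromosome 8, 25268042 to 25268331), followed by Ezh2, Btaf1 and Snap29.

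The Ezh2 region near the lower-coordinate end had ranks of 72.9 and 92.0 in the WT lists and 24.9 and 18.7 in the KO lists, a gap of 48.0 points. No region reached that gap in the 2 crossed splits, where the largest was 45.8. This cannot exclude random differences between libraries, because the margin is small and the test was chosen after this region had been seen. Regions near Tacc1 and Bmf had larger gaps between the genotypes. A shift shared by the gene or by the KO lists is argued against, as the median difference, WT minus KO, was -1.82 points over the other 2 Ezh2 regions and 60.6 at this one. Removal of the underlying DNA by Cre may account for the gap, which was number 2 of all regions ranking higher in WT, but peaks remained in both KO libraries and the labels do not place the floxed segment. Removal in part of the cells, a local loss of accessibility and a strain variant cannot be told apart from these lists.

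The excess of genotype-following regions was larger among strong calls, with a genotype ratio of 1.68 where both calls had a percentile of 50 or more. By count, only the WT pair, at 82, stood above the crossing pairs, at 22 to 46, and the KO pair, at 35, lay among them. With equal numbers of peaks the counts were 59 for the WT pair, 27 for the KO pair and 20 to 34 for the crossing pairs. Sex chromosomes are argued against as the source of the excess, since the smaller ratio on autosomes was 1.72 (lower bound 1.23). With equal numbers of called peaks the smaller ratio was 1.43, which met the criterion set beforehand for counting against unequal numbers as the source. Its interval began at 1.01, however, so unequal numbers stay open. Very narrow peaks stay open as well, because 11 of these regions had peaks of at least 200 bp, too few for a ratio, of which 8 followed genotype. The genotype itself may contribute, and this cannot be told apart from a handling difference between the pairs of libraries.

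On chromosome 6, which carries Ezh2, 99 of 506 regions called in 2 libraries were KO-only (19.6% against 14.9% elsewhere, Fisher's exact test, p = 0.00594, adjusted p = 0.218 over 42 tests). Strain DNA flanking the modified allele could raise that share near the gene, but within 5 Mb of Ezh2 it was 20.5% (9 of 44) and on the rest of the chromosome 19.5% (one-sided exact p = 0.504), too few regions to decide. Other explanations were not tested.

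A hypothesis stated before the ranks were tested was that regions of alternative activation genes rank higher in the KO lists. Their mean difference was 1.71 points over 132 regions (one-sided permutation p = 0.0477, adjusted two-sided p = 0.382), with 20 of 30 genes higher in KO. The one-sided p passed the criterion set in advance. However, the crossed splits gave -1.73 and 1.48 points, and the difference was 0.102 without KO replicate 1 and 3.31 without KO replicate 2. The hypothesis is therefore left open. A companion hypothesis was that regions of developmental regulators rank higher in KO. Their difference was -0.645 points over 54 regions (one-sided permutation p = 0.660). By the criterion set in advance, a negative difference counted against this hypothesis. The value lay within the range of matched random lists, from -2.83 to 2.54, so the hypothesis is left open as well.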
